A study of Mus musculus with 2 samples.

How the data were processed

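Mouse hearts that expressed FLAG-tagged NAT10 were studied by RNA immunoprecipitation sequencing (RIP-seq). NAT10 is the enzyme that acetylates cytidines in RNA. Per the labels' protocols, wild-type mice received an adeno-associated virus of serotype AAV9 under the skin at day 1 after birth. The virus carried FLAG-NAT10 behind the cTnT promoter, which is active in heart muscle cells. Hearts were taken 20 days after injection, about 60 mg of tissue was lysed, 10% of the lysate was kept as Input, and the rest was precipitated with anti-FLAG beads (RIP). Messenger RNA was purified from both fractions with a kit and sequenced as paired reads of 150 bases. The series held 1 Input library and 1 RIP library, so there were no replicates and no replicate check of any value, and no p-value was computed.

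Reads were trimmed with fastp and aligned with BWA 0.7.12, and MACS2 2.1.0 and HOMER were also named, per the submitters' processing notes. The deposited table listed summits, the single bases where RIP signal over Input peaked, with 1 line per overlapped gene. It held 2269 lines for 2020 summits in 1600 peaks, and 217 peaks had more than 1 summit. The score of each summit was deposited by the authors as a -log10 value of the peak caller. The header of that column had been replaced by a spreadsheet error, so it is not given whether it was a p-value or a q-value. The lowest score was 1.32, against 1.30 for the -log10 of 0.05. Scores were used only to describe, rank and filter summits within this list. The table gave no counts, fold enrichments or Input levels, so the depth of each library is unknown and enrichment could not be separated from abundance. The score of a summit can rise with both.

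The submitters' processing notes name the build GRCm39, but the positions in the table were those of GRCm38. Of 2140 gene lines matched by Ensembl identifier to GENCODE mouse release 39, 28.5% lay inside their gene on GRCm39. Of 1914 lines matched by symbol to the RefSeq genes of GRCm38, 98.9% lay inside their gene. All positions are therefore given as GRCm38, and no sequence or coordinate of GRCm39 was used. GENCODE supplied only gene names, gene types, exonic lengths and the lengths of untranslated regions (UTRs), for 973 of the 990 gene identifiers in the table. The sequence around summits, exon assignment from the reference annotation and finer bins along the spliced transcript, which had been planned, were not analysed here.

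Each summit was counted once and placed in 1 region, as the table gave it, in the order coding exon, 3' UTR, 5' UTR, exon of a non-coding gene, intron, no gene. The table appeared to use 1 transcript model per gene, which limits its exon and intron calls. It listed the strand of genes but not of reads, so summits shared by overlapping or antisense genes are uncertain. Shares were given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. Observed region shares were set against the share of bases in each part of the longest protein-coding transcript of the same genes, weighted by summit.

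The 34 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. For each list, the share of annotated protein-coding members with a summit was ranked among 10000 random lists of the same size, drawn from all 21770 protein-coding genes and matched on exonic length in 10 classes. These random lists were not restricted to genes expressed in the heart, because Input levels were not used here. A list was called above random when its share lay in the upper 2.5% of random lists. The median of the strongest score per gene was ranked among random sets of genes with a summit, where a list had at least 3. Tested on simulated data with lists of 40 genes, 1 of 100 lists was called with no change, 50 of 100 at a 3-fold share and 100 of 100 at a 10-fold share. Among lists made only of long genes with no change, 4 of 100 were called with length matching and 51 of 100 without it. No simulated list was chosen for expression in the heart, so these rates do not cover lists of expressed genes.

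Named genes were the 12 protein-coding genes with the highest score, the 5 with most summits (ties kept), Nat10 and Tnnt2, up to 4 members of each list with the strongest summit, and up to 4 members without a summit in list order. Some genes that this rule names are not reported here. Alternatives raised the score threshold to the median or the upper quartile, merged summits within 200 bases, left out the mitochondrial chromosome or summits in no gene, used only exon or UTR summits, dropped the length matching, took the median over a gene's summits, or used the transcript with the longest 3' UTR. Others were chosen after seeing the data. They used RefSeq GRCm38 gene bounds, the closest transcription start, the Ensembl canonical transcript, only summits in exactly 1 gene, the strongest summit per gene, and the list without Ttn. The closest transcription start need not belong to the gene that holds the summit, so it is a coarse assignment for RNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.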

Results

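RNA that came down with FLAG-NAT10 from mouse hearts was compared with Input RNA of the same lysate, with 1 library of each. The series held no pulldown from hearts without FLAG-NAT10. RNA held by the beads or the antibody therefore cannot be told apart from RNA bound to NAT10. The series asked which mRNAs are associated with NAT10 in the heart. The list held 2020 summits, and their scores (the authors' -log10 p or q) had a median of 12.5, with quartiles of 5.83 and 28.3 and a maximum of 4922. Sequencing depth is unknown, since the table holds no counts. With 1 library per group, every value below describes these libraries, and intervals cover counting error only.

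Nat10 itself (ENSMUSG00000027185), the gene of the bait, had 3 weak summits on chromosome 2 in GRCm38. Their scores were 5.28 at 103726120 in exon 24, 2.85 at 103754148 in exon 4 and 2.07 at 103724092 in the last intron. Reads from RNA of the FLAG-NAT10 construct may align to Nat10 exons, and the table cannot tell them from reads of the mouse gene. Tnnt2, cardiac troponin T, whose promoter drove the construct, had no summit in the table's own gene assignment. A summit with a score of 35.9 at 135852139 on chromosome 1, which the table placed in no gene, lay inside the RefSeq GRCm38 bounds of Tnnt2. The list of these 2 genes was not called (1 of 2, percentile 93.6), but had 2 of 2 and was called under RefSeq bounds (percentile 99.8) and under the closest transcription start. At the median score threshold and at the upper quartile it had 0 of 2, at percentiles 46.9 and 48.8.

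Of the 12 protein-coding genes with the highest score, 6 were encoded by the mitochondrial genome. mt-Nd2 led with 4922 at position 4716, followed by mt-Nd6 with 3671 at 13836, mt-Nd5 with 2175 at 13308, mt-Nd4 with 1857 at 11303, mt-Cytb with 1667 at 14999 and mt-Nd1 with 955 at 3460. The mt-Nd6 summit belonged to the same peak as the 3 summits of mt-Nd5, its neighbour on the other strand, so the signal cannot be assigned to either gene with certainty. Of the 7 complex I genes 5 had a summit, and none of the 3 cytochrome oxidase genes (mt-Co) or the 2 ATP synthase genes (mt-Atp) had a summit. mt-Nd3, mt-Nd4l, mt-Co1 and mt-Co2 were among the members without one. Scores can rise with abundance, so the high ranks of mitochondrial genes do not separate abundance from association with NAT10.

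Among nuclear genes, Myh6 (ENSMUSG00000040752), the alpha myosin heavy chain of the heart, had the highest score, 1524 at 54950479 on chromosome 14 in exon 26. It had 22 summits. Its close paralog Myh7 had none, and reads shared between these similar genes make the split between them uncertain. Tnnc1, cardiac troponin C, scored 351 at 31211519 on chromosome 14 in its last exon. Lpl, lipoprotein lipase, scored 391 at 68905702 on chromosome 8 in the 3' UTR. Naca, a subunit of the nascent polypeptide-associated complex, scored 350 at 128041683 on chromosome 10, and its 8 summits all lay in exon 3. Zc3h7a, a zinc finger gene, scored 681 at 11144118 on chromosome 16, where the table placed the summit in intron 19.

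Ttn (ENSMUSG00000051747), the giant spring protein of the sarcomere, had 235 summits, 11.6% of the list. Of these, 228 lay in exons, 5 in introns and 2 in the 3' UTR. Its highest score was 297 at 76774734 on chromosome 2, placed in intron 276 of the table's transcript model. The antisense gene Gm13938 overlapped 112 of the Ttn summits, and the 2 strands cannot be told apart in this table. Of these 112, 111 lay in introns of Gm13938 and 1 in an exon, whereas most Ttn summits lay in Ttn exons. Ryr2, the calcium release channel, followed with 58 summits and a highest score of 160. Ahnak, a giant scaffold protein, had 30, Cmya5 had 25, and Pde4dip, Myh6, Dync1h1 (the dynein heavy chain) and Dst had 22 each.

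**Figure D1:**
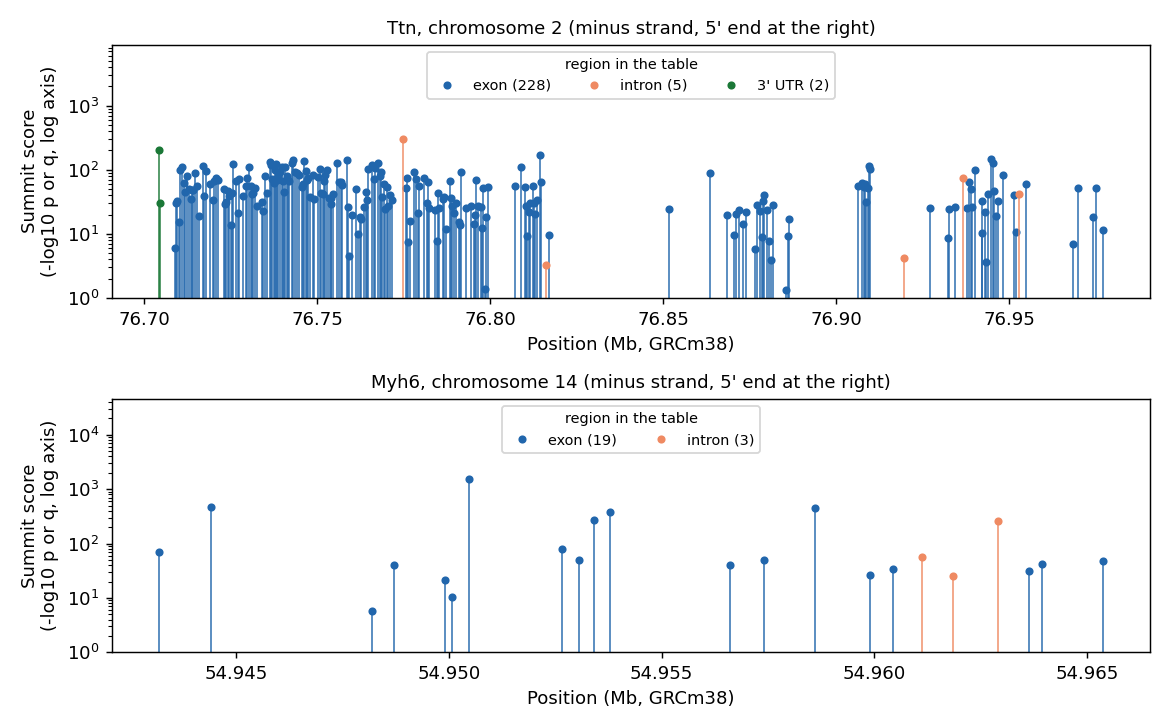
Summit score (-log10 p or q, log axis) against GRCm38 position in megabases for Ttn on chromosome 2 and Myh6 on chromosome 14, 1 line and point per summit, coloured by the region the table gives. The 235 Ttn summits spread along the gene with a highest score of 297, while the 22 Myh6 summits reach 1524.

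In all, 919 protein-coding genes had a summit, 4.22% of the 21770 annotated. Of these, 642 had exactly 1 summit, 227 had 2 to 4 and 50 had 5 or more. The median of the strongest score per gene was 14.2, with quartiles of 6.97 and 28.2. A further 42 genes were lncRNA genes, counted for any overlap with a summit, introns included. The number of summits and genes depends on the threshold of the list, since 498 genes had a summit at or above the median score and 226 at or above the upper quartile.

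Lists of heart muscle genes had high shares of members with a summit. Random lists were drawn from all protein-coding genes, expressed in the heart or not, so a call can reflect expression alone. Summits were found in 18 of 42 sarcomere genes (42.9%, interval 27.7 to 59.0), and none of 10000 length-matched random lists held as many. After Myh6, Tnnc1 and Ttn, the strongest member was Myom2, an M-band protein, with 233 in its 3' UTR. Myh7, Myh7b, Actc1 and Acta1 were among those without a summit. The list of calcium handling and ion channels had 13 of 36 (36.1%, 20.8 to 53.8), also more than any random list. That share was 16.7% at the upper quartile of scores and 13.9% under the closest transcription start, and the list was still called. Its strong members included Ryr2 at 160, junctophilin Jph2 at 95.2 and triadin Trdn at 79.8, while Pln, Cacnb2, Asph and Hrc had none. Of the intercalated disc and costamere list, 6 of 23 had a summit (26.1%, 10.2 to 48.4, percentile 99.8), with Ctnna1 at 107, desmoplakin Dsp at 98.7 over 18 summits, Popdc2 at 88.7 and beta-catenin Ctnnb1 at 13.3. The list had 3 of 23 at the upper quartile and 17.4% both at the median score and under the closest transcription start, and the call held.

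Transcription factors of the heart had a summit in 8 of 30 cases (26.7%, 12.3 to 45.9), a count that 2 of 10000 random lists reached. The highest scores were 105 for the coactivator Ppargc1b, 39.3 for Nkx2-5, 28.2 for Gata4 and 25.9 for Myocd. At or above the upper quartile of scores this list fell to 6.67% and percentile 96.8, and it had 13.3% both at the median score and under the closest transcription start. The natriuretic and fetal gene list had 3 of 17 (17.6%, 3.80 to 43.4, percentile 97.0), and these were Xirp2 at 51.6, Gata4 and Myocd. It was not called, but at the median score threshold, with 3 members still counted, it lay at percentile 99.4, and without length matching at 98.1, against 88.9 at the upper quartile. Nppa and Nppb, the natriuretic peptide genes, had no summit.

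Genes of fuel metabolism had summits in 4 lists, whose intervals overlapped. Of fatty acid oxidation and uptake genes, 9 of 28 had a summit (32.1%, 15.9 to 52.4), and of glycolysis genes 9 of 22 (40.9%, 20.7 to 63.6), and no random list held as many in either case. The first list was led by Lpl, the fatty acid binding protein Fabp3 at 223, Acadvl at 66.8 and Mlycd at 57.5, and lay at percentile 96.5 with 10.7% when genes were assigned by the closest transcription start, and at 17.9% at the upper quartile. The second was led by pyruvate kinase Pkm at 141, Gpi1 at 114, the muscle glycogen phosphorylase Pygm at 84.7 and hexokinase Hk2 at 40.7, and its share was 18.2% at the upper quartile. The tricarboxylic acid cycle had 4 of 19 (21.1%, 6.05 to 45.6, percentile 98.9), led by Sucla2 at 75.8, Ogdh at 55.7 and Dld at 15.1, and 10.5% at the upper quartile. Creatine kinases and shuttles had 3 of 15 (20.0%, 4.33 to 48.1, percentile 98.5), namely the ADP/ATP carrier Slc25a4 at 248, Got1 at 52.9 and Ckmt2 at 1.45. This last list was not called at the median score threshold (percentile 97.1) or under the closest transcription start (95.5), but was called at the upper quartile (2 of 15, percentile 99.4) and under RefSeq bounds (99.8).

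Respiratory chain genes are encoded in the mitochondrion and in the nucleus. Of the 13 mitochondrial genes 6 had a summit (46.2%, 19.2 to 74.9), more than in any random list. Of 79 nuclear genes 6 had one (7.59%, 2.84 to 15.8, percentile 97.3), and these included Ndufs1 at 17.4, Ndufa2 at 16.4, Cox5a at 8.18 and Cox6b1 at 5.53. The nuclear list was not called, but lay at percentile 98.2 when only exon or UTR summits counted. Under the closest transcription start the shares were 15.4% (1.92 to 45.4) and 6.33% (2.09 to 14.2), with overlapping intervals, and the difference was not tested. The median of the strongest scores was 2016 in the mitochondrial list and 6.86 in the nuclear list, against 14.2 over all genes with a summit. The random lists were matched on length and not on abundance, which can also raise scores. Neither the shares nor the scores therefore separate binding from abundance.

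Genes of translation and protein folding were also represented. Translation factors had a summit in 9 of 34 cases (26.5%, 12.9 to 44.4), above every random list. Their strongest members were Eif4g1 at 152, Eef1a2 at 21.5, Eif4g2 at 21.0 and Eif5b at 18.8. The share was 11.8% at the median score threshold and 14.7% under the closest transcription start, where the list was still called. At the upper quartile of scores the share was 2.94%, at percentile 80.0. Chaperone and stress genes had 7 of 30 (23.3%, 9.93 to 42.3), again above every random list, with Hsp90ab1 at 170, Bag3 at 84.9, Hspa9 at 57.5 and Hspa8 at 35.8, but at percentile 86.6 under the closest transcription start. The ubiquitin, proteasome and autophagy list had 6 of 35 (17.1%, 6.56 to 33.6, percentile 99.6), with Psmd2 at 45.9 and Nedd4 at 40.7 among them, and fell to percentile 16.5 under the closest transcription start. Splicing factors had 9 of 42 (21.4%, 10.3 to 36.8, percentile 99.9), led by Son at 130 and Celf2 at 28.0, with percentile 96.0 at the median score threshold and 69.4 at the upper quartile. The insulin, AKT and mTOR list had 8 of 25 (32.0%, 14.9 to 53.5, a count that 5 of 10000 random lists reached), led by Akt1 at 19.9 and Foxo1 at 13.3 with a median strongest score of 6.94, and lay at percentile 95.1 and 31.8 under the same thresholds, and at 96.6 under the closest transcription start.

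Other lists stood within the random range. Of large-subunit ribosomal proteins 1 of 48 had a summit (2.08%), Rpl13 at 5.07, and of small-subunit proteins 0 of 32. Ribosome biogenesis had 3 of 36 (8.33%, percentile 83.5), and these were Ubtf at 18.4, Nat10 and Ddx21 at 4.72. RNA modification enzymes and readers had 3 of 28 (10.7%, percentile 83.3), which were Zc3h13, Ythdf3 and Nat10. Nat10 counts in both lists, although its exon summits may come from RNA of the construct. Cell cycle genes had 1 of 30 (Ccnd2 at 5.21), p53 and apoptosis genes 1 of 24 (Bcl2l1 at 15.0) and replication-dependent histones 1 of 22 (H1f2 at 27.0). None of 4 genes listed beforehand as reported NAT10 targets, Cd47, Rcan2, Uhrf1 and Kmt5a, had a summit (interval 0 to 60.2%, percentile 40.5). A list of 4 genes is too small to tell this from random lists. Of the 34 lists, 16 were called above random and 0 lay below the 2.5th percentile, and lists overlap in their members. A list without any summit can still lie above that bound, as the small-subunit ribosomal proteins did at percentile 23.4. The lack of lists below it therefore does not show that none was depleted. Nor does a call above random separate association with NAT10 from expression in the heart.

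**Figure D2:**
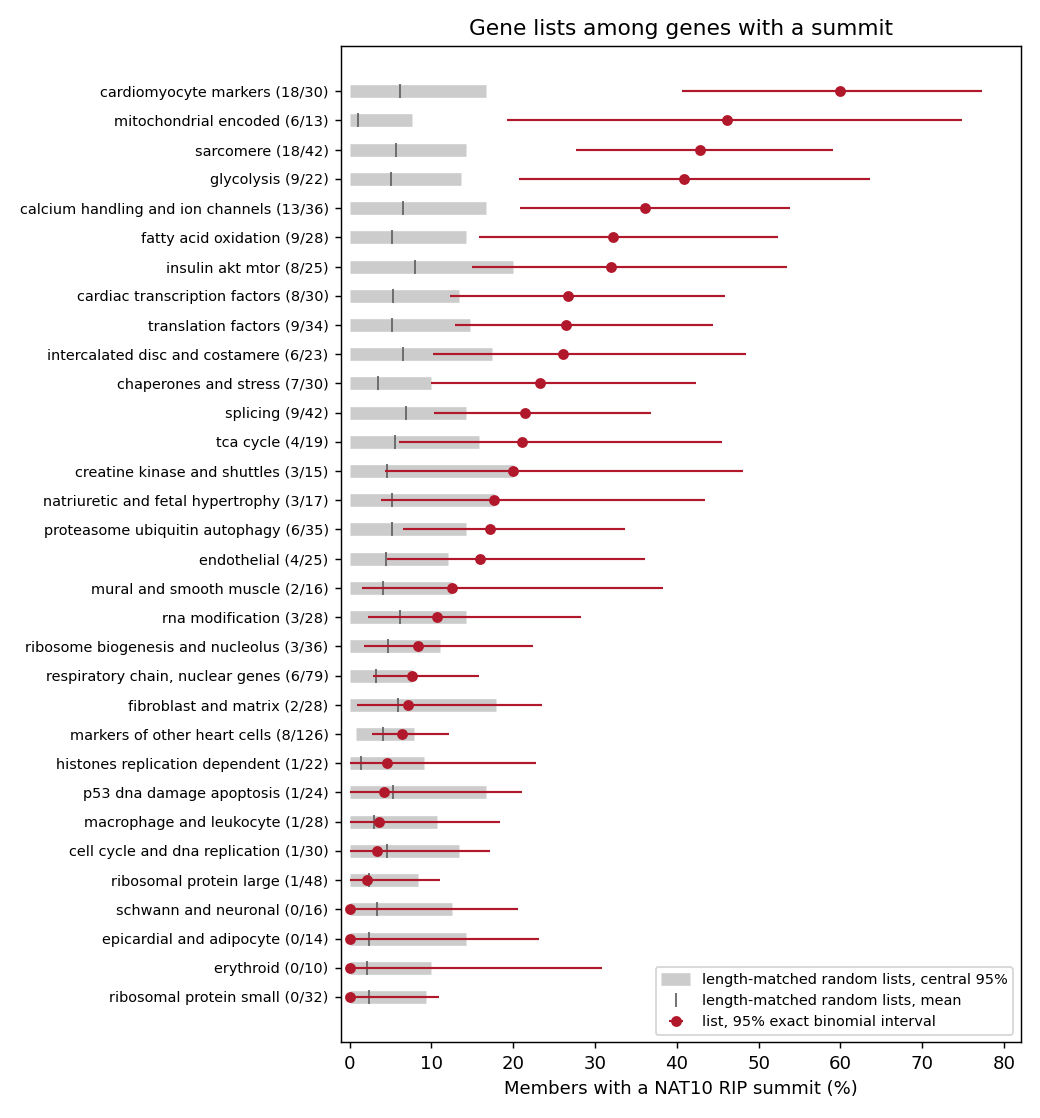
Share of list members with a summit, in percent, for 32 gene lists (red points, with exact 95% binomial intervals) beside the mean and the central 95% of 10000 length-matched random lists (grey). Cardiomyocyte markers reach 60.0%, and markers of other heart cells 6.35%.

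Because FLAG-NAT10 was expressed from a cardiomyocyte promoter, markers of cardiomyocytes were compared with those of the other cells of the heart. Summits were present in 18 of 30 cardiomyocyte markers (60.0%, 40.6 to 77.3) and in 8 of 126 markers of other cells (6.35%, 2.78 to 12.1), a list that held neither Des nor the erythroid genes given below. Their intervals did not overlap. The cardiomyocyte share exceeded all 10000 random lists, and the share of the other cells lay at percentile 89.5. Actc1, Tnnt2, Myl2 and Myl3 were cardiomyocyte markers with no summit in the table's own gene assignment. Under RefSeq bounds, the summit described above lay inside Tnnt2. By cell type, endothelial markers had 4 of 25 (16.0%, 4.54 to 36.1, percentile 98.7), namely Cldn5 at 23.4, Eng at 20.2, Fabp4 at 8.29 and Flt1 at 5.12, and this list lay at percentile 92.4 at the median score threshold and 89.5 under the closest transcription start, with 0 members left at the upper quartile. Mural and smooth muscle markers had 2 of 16 (12.5%), Des, which cardiomyocytes also express, at 60.8 and Pdgfrb at 18.1, and lay at percentile 92.2, at 97.9 at the median score threshold, where it would be called, and at 92.1 at the upper quartile. Fibroblast and matrix markers had 2 of 28 (7.14%), Col1a1 at 24.9 and Pdgfra at 4.10, and macrophage and leukocyte markers 1 of 28, Cd74 at 2.69. Erythroid (0 of 10), Schwann and neuronal (0 of 16) and epicardial and adipocyte markers (0 of 14) had none. The table lists only summits past its threshold, so no summit does not mean no RNA.

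The median of the strongest score was 89.8 (28.3 to 223) in the cardiomyocyte list and 13.2 (2.69 to 24.9) in the list of other cells. The sarcomere list had 98.9 (51.6 to 169). Both muscle lists exceeded random sets of genes with a summit, at percentile 100, whereas the other cells lay at 42.9. Long genes with many summits can reach a higher maximum. With the median over each gene's summits the values were 15.4 for cardiomyocyte markers (percentile 88.1) and 18.6 for the sarcomere (percentile 96.4), so that neither list was then called.

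Summits lay mainly in coding exons and 3' UTRs. Coding exons held 1022 summits (50.6%, 48.4 to 52.8), 3' UTRs 736 (36.4%, 34.3 to 38.6), 5' UTRs 34 (1.68%, 1.17 to 2.34), introns 116 (5.74%, 4.77 to 6.85) and exons of non-coding genes 22 (1.09%), and 90 lay in no gene (4.46%). Without the Ttn summits, exons held 44.5% and 3' UTRs 41.1%. Median scores were 12.4 in coding exons, 13.2 in 3' UTRs and 7.70 in introns. Without Ttn they were 8.99, 13.1 and 7.62.

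Within mRNAs, 3' UTRs held more summits than their share of bases would give. That share counts bases only, with no allowance for where reads could align or for Input coverage along the transcript. The comparison took 1767 summits that lay in an exon or UTR of exactly 1 coding gene, without the mitochondrial chromosome (840 genes). Of these, 41.3% lay in the 3' UTR, against 29.5% of the bases of the longest coding transcripts, a ratio of 1.40 (1.32 to 1.48). Coding exons held 56.8% against 62.3% (0.91, 0.87 to 0.95) and 5' UTRs 1.92% against 8.20% (0.23, 0.16 to 0.33). With the transcript of the longest 3' UTR instead, the 3' UTR ratio was 1.07 (1.01 to 1.13), and the coding exon ratio turned from a deficit to 1.05 (1.003 to 1.089, 56.8% against 54.3%). The size of the 3' UTR excess and the direction for coding exons thus depend on the transcript chosen. These intervals treat summits of the same gene as independent and may be too narrow. The small departures from 1 with the longest 3' UTR are therefore not secure. Of the strongest summit per gene, 69.3% lay in the 3' UTR against 41.5% of the bases of the longest coding transcripts. That comparison was not run with the longest 3' UTR, so its size may also depend on the transcript chosen.

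**Figure D3:**
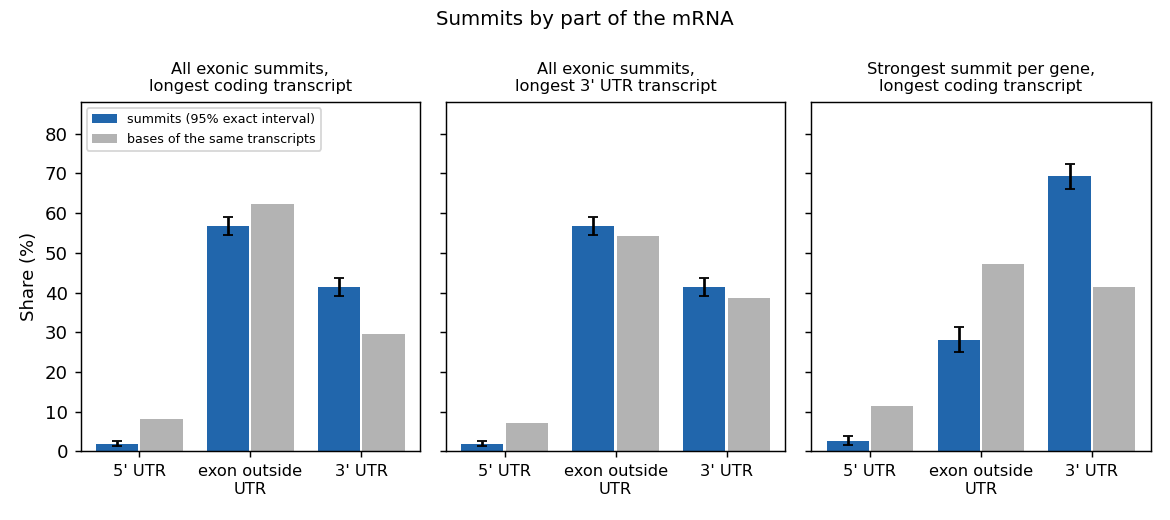
Share of exonic summits (blue, percent, with exact 95% intervals) and of transcript bases (grey) in the 5' UTR, the exon outside the UTRs and the 3' UTR, for all summits with 2 choices of transcript and for the strongest summit of each gene. The 3' UTR holds 41.3% of summits against 29.5% of bases with the longest coding transcripts, and 69.3% of strongest summits.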

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

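The test of mRNA abundance, the interval placed on the length ratio and the check of what the ribosomal protein test was able to decide were chosen only after the results were seen. Without these last additions, the length ratio would have counted against its explanation and the ribosomal protein share in favour of its own.

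Several summits with high scores lay on non-coding RNAs outside the mRNA comparison, although messenger RNA had been purified. Rn7sk, the 7SK RNA that binds the elongation factor P-TEFb, scored 471 at 78175468 on chromosome 9, rank 10 among all summits. Rpph1, the RNA of RNase P, scored 153 at 50807609 on chromosome 14. Rn18s-rs5, an 18S ribosomal RNA copy, scored 143 at 39847748 on chromosome 17, and Rmrp, the RNA of RNase MRP, scored 124 at 43492915 on chromosome 4. Of the 90 summits that the table placed in no gene, 68 lay inside a protein-coding gene of RefSeq GRCm38, among them Pfn1 at 94.1.

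Cardiomyocyte markers had a summit more often than markers of other heart cells. Transcript length did not account for it, since the share lay at percentile 100 among length-matched lists. The gene assignment of the table did not either, since with RefSeq bounds the lower bound of the cardiomyocyte share was 47.2%, above the upper bound of 13.1% for the other cells. Abundance of cardiomyocyte mRNAs in the lysate stays open, because the nuclear respiratory chain share of 7.59% overlapped that of the other cells and Input levels were not used here. Binding by a bait made in cardiomyocytes, which the design names, also stays open and was not tested.

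Longer mRNAs had a summit more often, from 1.22% of genes in the shortest of 5 length classes to 9.46% in the longest. If more bases were the whole cause, summits per exonic kilobase were predicted to differ by at most 1.5 times between these classes, a bound written before the densities were computed. The ratio was 2.16 (1.38 to 3.53 from 1000 resamplings of genes), and 1.76 (1.26 to 2.54) without Ttn. Both values pass the bound and both intervals include it, so the explanation cannot be told apart from a higher density in long mRNAs. This test counts summits, not genes with a summit. Genes with a summit per exonic kilobase went from 0.0094 in the shortest class to 0.0075 in the longest. The share of genes thus rose no faster than exonic length, a measure that the prediction did not name. No biological explanation was tested.

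Ribosomal protein mRNAs rarely had a summit, 1 of 80 (1.25%, 0.0316 to 6.77). The prediction for short transcripts as the cause, written before the test, was a share at or above the 2.5th percentile of length-matched lists, and it lay at 27.7. That test could not have come out the other way, since 0 of 80 would still have lain at percentile 6.90, so it decides nothing. No biological explanation was tested.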

How the results depend on the processing

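The RefSeq, closest-start, canonical-transcript, exactly-1-gene, strongest-summit and without-Ttn settings were chosen after seeing the data. The coding exon ratio reversed, from 0.91 to 1.05 with the transcript of the longest 3' UTR. At or above the median score there were 1011 summits in 498 coding genes, and at or above the upper quartile 505 in 226, as fewer summits were kept by construction. At the upper quartile, coding exons held 55.2% and 3' UTRs 34.3% of summits. Without Ttn these were 44.5% and 41.1%, and with summits in exactly 1 gene 3' UTRs held 40.3%. Markers of other cells had a summit in 0% at the upper quartile and in 2.38% under the closest transcription start, while cardiomyocyte markers ranged from 43.3% to 66.7% over all settings. The 3' UTR ratio was 1.07 with the longest 3' UTR, 1.49 with the canonical transcript, 1.65 at the median score, 1.74 at the upper quartile and 1.67 for the strongest summit per gene. The ratios at both score thresholds and for the strongest summit used only the longest coding transcript. The median score fell to 15.4 for cardiomyocyte markers and 18.6 for the sarcomere with the median over each gene's summits. Lists called above random numbered from 11 to 17, and the proteasome list had 0 of 35 members with a summit under the closest start. That setting gave 626 coding genes against 919, and it can name a gene that does not hold the summit. A lower share under it may therefore come from the assignment. Of the 32 lists other than the cardiomyocyte and other-cell markers, shares moved outside their interval for 17 at the upper quartile, 10 under the closest start (the proteasome list among them), 8 at the median score and 2 under RefSeq bounds. The cause was not tested, except where fewer summits were kept. The mitochondrial list has no RefSeq value, because its symbols differ there. The sequence windows and CXX runs, exon assignment and region from the reference annotation, another measure per summit and all transcripts that hold a summit were not run. No paired analysis was possible because each group held 1 library. Depth is unknown, so its effect on genes without a summit could not be assessed.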

Other observations

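Some strong summits lay in genes outside the lists and outside the rule for named genes, and were chosen after their values were seen. Nrap, a protein of the muscle attachment region, and the neighbouring gene Habp2 shared a summit with a score of 215 at 56320172 on chromosome 19. Mrpl12, a protein of the mitochondrial ribosome, had one at 170, and the transcription factor Sox4 one at 153, each shared with an overlapping gene that has no GENCODE match. Summits per exonic kilobase were between 0.0089 and 0.0105 in the 4 shorter length classes and 0.0227 in the longest, while genes with a summit per exonic kilobase went from 0.0094 in the shortest to 0.0075 in the longest. Among markers of at most 4704.5 exonic bases, 4 of 10 cardiomyocyte genes and 2 of 68 genes of other cells had a summit, and among longer ones 14 of 20 and 6 of 58.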
